A study of Rattus norvegicus with 6 samples.

How the data were processed

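RNA was extracted from corneas with a kit for fibrous tissue and sequenced as 150 bp paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols. The deposited values used here are raw gene counts, whole numbers that are not normalized, and FPKM values for the same 17771 genes, per the file headers and the values. The authors deposited FPKM also as single-library files, which equalled the FPKM table in 6 of 6 libraries. The submitters' processing notes name the genome build mRatBN7.2, R 3.2.0 and DESeq2, with no role for each. The aligner, the counter, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. In the count table a separator was missing between names in the header, and columns were assigned by name. As a check, the log2 ratio of count to FPKM over abundant genes, relative to that of control 1, had an SD of at most 3.03e-10 for a library's own columns and at least 0.248 for columns of different libraries. The count table lists only genes with at least 1 count over all libraries, and 635 genes have exactly 1. Of the symbols, 16144 matched a RefSeq symbol of the rat assembly GRCr8 and 404 matched only a synonym; this table was used for names alone.

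The 6 libraries fall into control (saline) and resveratrol with 3 each, as the treatment label gives them. The sample descriptions end in Sep for replicate 1 of both groups and in Oct for the other 4 libraries, and the labels do not state what the endings mean. Total counts were 35068936, 36947871 and 37460756 in control and 37301669, 36904770 and 37023639 in resveratrol, so depth was similar in all libraries. Counting error is relatively largest for genes with few counts. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 32.7 to 96.5), so no library was treated as a repeat deposit of another; repeat libraries of a single cornea would differ by more than this noise as well.

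Counts were filtered with filterByExpr at its default settings, which left 14213 genes, scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, resveratrol against control, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genes left out held 0.0237% of the counts. Standard errors of log2 fold changes come from limma 3.58.1 (trend) on log2 CPM with a prior count of 2. Their variances are moderated toward a trend with abundance over all genes, so they can differ from the spread of a gene's own libraries. They stand beside edgeR's fitted fold change. DESeq2 1.42.0 gave adjusted p-values for 14666 genes and none for 3105. Gene lists were tested with camera at a preset correlation of 0.01 and, beside it, with camera at an estimated correlation and with fry, each adjusted over the tested lists. With 3 against 3 libraries an exact permutation test of a single value cannot go below 0.1, so no such test was made.

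The main tests, the gene lists, the rule for named genes and the alternatives below were chosen before the data were examined. Named genes were to be the 10 higher and 10 lower genes with the largest fold change among genes that passed, and the 5 with the smallest p-value in each direction; none passed, so the 10 genes with the smallest p-value in each direction were taken, leaving out symbols that are only a locus or clone identifier. To these were added from each list the 2 tested members with the highest mean CPM, and a fixed set (Krt12, Cd3e, Cd8a, Cd68, Ifng, Il1b, Tnf, Vegfa, Vegfc, Pecam1, Lyve1 and Sirt1). Some genes that this rule names are not reported here. Alternatives covered other scaling factors, no filter and a stricter filter, DESeq2, limma voom, robust edgeR, the replicate number as a block, the Sep or Oct ending as a covariate, the Oct libraries alone, limma on log2(FPKM + 1) or log2(FPKM + 0.1), leaving out each library, and thresholds of 0.01 and 0.1. Added only after the data were seen were edgeR with bias-adjusted deviances, edgeR's likelihood ratio test, removal of a gene length trend (lowess span 0.3) and DESeq2 under other designs and without each library.

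The tests were tried on simulated counts with the means, depths and dispersions of 14213 genes, 200 of them changed. For resveratrol against control, edgeR recovered 17.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold, and 6 of its 121 calls were unchanged genes. DESeq2 recovered 41.8%, 79.1% and 95.5%, and 41 of its 185 calls were unchanged genes. With no gene changed, edgeR called 1 and DESeq2 19. A simulated fall of the 17 macrophage markers was found by camera with the preset correlation (adjusted p = 2.12e-20) and with an estimated correlation (adjusted p = 0.0179), and 0 other lists were called. The simulated genes were independent, whereas the correlation estimated for the real macrophage list was 0.547. This trial therefore does not show how camera performs on correlated lists. Figures were drawn with matplotlib 3.10.9.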

Results

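Gene expression was measured by bulk RNA sequencing in corneas of Wistar rats that had received a corneal allograft from Sprague-Dawley (SD) donors. Recipients were given daily intraperitoneal injections of resveratrol, a plant polyphenol, or of saline, and the corneas represent day 7. The series holds 3 resveratrol libraries and 3 saline libraries, called control here. The comparison asks which genes differed between resveratrol and saline in grafted corneas, in a study whose title concerns rejection of the graft. Total gene counts per library ranged from 35068936 to 37460756, and 16267 to 16446 of the 17771 listed genes had at least 1 count in a library. The groups did not overlap in this number, which was 16433 to 16446 in control and 16267 to 16346 in resveratrol. The 20 most counted genes took 16.4% ± 0.659 of the counts in control and 16.3% ± 0.563 in resveratrol (SD, n = 3). Levels below are TMM-scaled CPM, as mean ± SD with n = 3 per group. Log2 fold changes are resveratrol minus control ± moderated standard error. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Genes are given by symbol without coordinates, since no genome was used here.

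Lists of macrophage, dendritic cell, T cell, MHC class II, interferon, blood vessel and fibrous matrix genes fell in resveratrol corneas by camera with its preset correlation, though not with an estimated correlation (smallest adjusted p = 0.389). Cd74, the invariant chain of MHC class II, was at 396 ± 156 CPM in control and 165 ± 22.8 CPM in resveratrol. Col1a1, a chain of type I collagen, was at 7044 ± 2112 and 3593 ± 924 CPM, and Pecam1, an endothelial junction protein also called CD31, at 81.5 ± 24.4 and 48.8 ± 8.94 CPM. Scd, which makes monounsaturated fatty acids, had a higher mean in resveratrol, at 23.5 ± 6.81 and 80.9 ± 26.4 CPM. Krt12, the keratin of corneal epithelium, was at 34169 ± 1076 and 35071 ± 2934 CPM, and its means differed by less than either SD.

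Of the 14213 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.1002. At an unadjusted p under 0.05 edgeR gave 2782 genes, 1115 higher and 1667 lower, where chance gives about 711. DESeq2, run as an alternative, called 1007 genes, 327 higher and 680 lower, and 274 of these differed at least 2-fold, 18 higher and 256 lower. In the simulated counts 41 of 185 DESeq2 calls were unchanged genes, against 6 of 121 for edgeR. A likelihood ratio test in edgeR, added after the data were seen, called 829, and limma voom called 0. The groups did not overlap in CPM for 3769 genes, 26.5% of those tested, where chance gives 10%. Of the DESeq2 calls, 1002 were tested in edgeR, all with the same sign, and 982 of these had no overlap. Both tools used the same counts, so this is no independent support. Without control 3, edgeR called 21 genes, all lower, of which 10 were on the type I interferon list, and without resveratrol 2 it called 1, the gelatinase gene Mmp9, named after its values were seen (-1.33 ± 0.26 with all libraries). The DESeq2 count was 623 without control 1, 390 without control 2, 530 without resveratrol 1 and 642 without resveratrol 2, and without control 2 the edgeR count at an unadjusted p under 0.05 was 1811. In the Oct libraries alone (control 2 and 3 with resveratrol 2 and 3) DESeq2 called 404 genes and edgeR 0.

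The first principal component held 40.0% of the variance of log2 CPM, with the control libraries at negative and the resveratrol libraries at positive scores. Control 3 lay nearest to the resveratrol libraries, at -7.46, against -38.1 for control 1 and -28.8 for control 2. The resveratrol scores were 37.3, 20.3 and 16.8. Spearman correlation across genes, which are not independent replicates, was 0.985 to 0.990 within control, 0.987 to 0.992 within resveratrol and 0.976 to 0.991 between the groups, so these ranges overlapped.

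**Figure D1:**
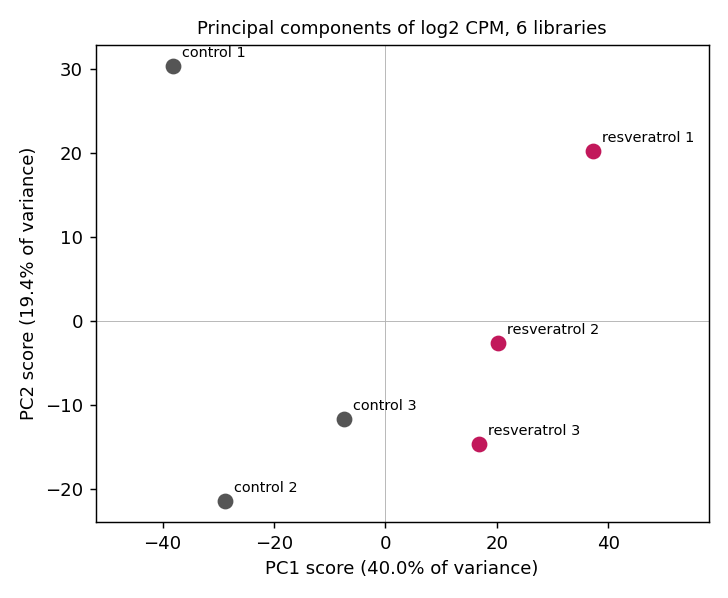
Scores of the 6 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis; gray points are control and red points resveratrol. The groups separate on the first component (40.0%), and control 3, at -7.46, is the control library nearest to the resveratrol side.

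The genes with the smallest p-values had an edgeR adjusted p of 0.1002 each and so did not pass, while DESeq2 called all 20 of them and none overlapped between the groups. They were chosen by p-value on the same counts, so neither is independent support. Among the lower genes, Chchd2, which encodes a mitochondrial intermembrane space protein, was at 12.9 ± 5.70 CPM in control and 1.63 ± 0.368 CPM in resveratrol (log2 fold change -2.98 ± 0.33, DESeq2 adjusted p = 1.19e-13). Several gene copies and pseudogenes of similar name are listed in the rat RefSeq table, so its level is uncertain. Without control 3 its edgeR adjusted p was 0.0326, and over the other edgeR quasi-likelihood fits it was between 0.0864 and 0.280. Cyba, a subunit of the phagocyte NADPH oxidase, was at 47.5 ± 1.75 and 24.6 ± 3.72 CPM (-0.95 ± 0.12). Matrix-processing genes in this set were Loxl2, which crosslinks collagen (-0.67 ± 0.091), Fkbp10, a collagen chaperone (-0.61 ± 0.081), and Pxdn, which crosslinks collagen IV (-0.96 ± 0.13). The other lower genes were Ncam1 (-0.70 ± 0.090), Limd2 (-1.07 ± 0.15), Rasa4 (-2.03 ± 0.27), Id3 (-0.60 ± 0.085) and Fst, which binds activin (-0.76 ± 0.11). Among the higher genes, Scd (1.78 ± 0.28), Fads2, a fatty acid desaturase (0.99 ± 0.16), and Lpcat3, which remodels phospholipids (0.58 ± 0.093), act in lipid metabolism. Mdn1 (0.77 ± 0.10) and Heatr1 (0.64 ± 0.096) act in ribosome assembly. Garem1 (0.58 ± 0.074), Plscr1 (0.97 ± 0.15), Cerk (0.58 ± 0.089), Bach1 (0.46 ± 0.070) and E2f4 (0.48 ± 0.078) were also higher.

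Of the 42 gene lists fixed beforehand, 37 had at least 3 tested members, and 15 passed camera with its preset correlation, 14 lower and 1 higher in resveratrol. With an estimated correlation 0 passed (smallest adjusted p = 0.389), and 0 passed by fry, which tests whether a list's genes move on balance in a single direction (smallest adjusted p = 0.0764). By fry's test for change in either direction, which does not compare a list with other genes, 15 passed (smallest adjusted p = 0.00422), 10 of them among the camera calls. The others that passed were the lymphatic endothelial, heat shock, NF-kB, sirtuin and corneal endothelial lists. Camera calls that missed this fry test were MHC class II (adjusted p = 0.0506), macrophage (0.0610), T cell (0.0945), interferon gamma (0.152) and cell cycle (0.406). These lists passed only camera with its preset correlation. Another split of the same 6 libraries, which put control 3 with resveratrol 1 and 2, moved 17 lists by camera with the preset correlation. In the Oct libraries alone camera moved 16 lists, 15 of them lower, and the Sep libraries, 1 per group, allow no test. No member of any list passed edgeR's adjustment over all genes, so counts adjusted over the list alone are given for the lists. Members named as passing that adjustment were chosen after their values were seen.

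**Figure D2:**
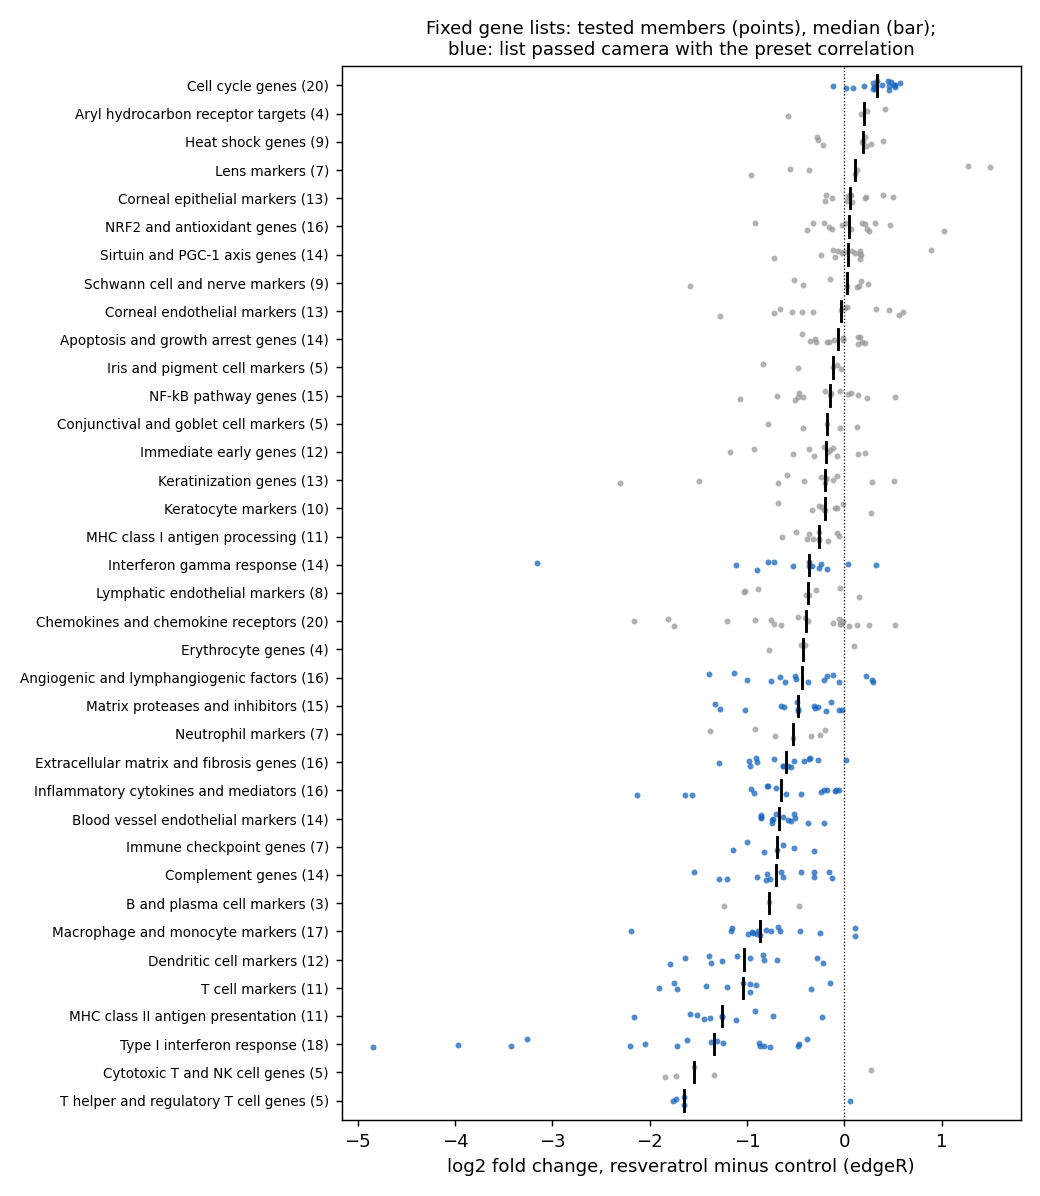
Log2 fold change (resveratrol minus control, horizontal axis) of each tested member (points) of 37 gene lists, with the list median as a bar; blue lists passed camera with the preset correlation and gray lists did not, and tested members are in parentheses. The immune, vessel and matrix lists in blue have medians from -1.65 to -0.36, and cell cycle genes lie right of 0 at 0.33.

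All 11 tested T cell markers had lower means in resveratrol (median log2 fold change -1.04), and the list fell by camera (camera adjusted p = 0.000233; adjusted p = 0.432 with an estimated correlation). Lck, the T cell receptor kinase, was at 3.89 ± 1.69 CPM in control and 1.99 ± 0.334 CPM in resveratrol, Cd3e, a chain of the T cell receptor complex, at 1.58 ± 1.02 and 0.417 ± 0.240 CPM (edgeR adjusted p = 0.170, DESeq2 0.0476), and Tcf7 at 10.8 ± 1.73 and 8.58 ± 0.761 CPM. Of the T cell markers 2 were lower adjusted over the list alone, Cd5 and Cd2. Macrophage, T cell and dendritic cell markers together had median deviations from their mean log2 CPM of 0.85, 0.41 and 0.071 in control libraries 1, 2 and 3 and of -0.75, -0.39 and -0.096 in resveratrol, so control 3 and resveratrol 3 lay nearest to each other. The 5 T helper and regulatory T cell genes fell as a list (median -1.65; camera adjusted p = 0.00502; adjusted p = 0.389 with an estimated correlation), and 4 passed adjusted over the list alone, Icos, Foxp3, Il2ra and Gata3. DESeq2 called 2, Icos and Foxp3. Foxp3, Il2ra and Gata3 had few counts, with means of 0.900, 1.05 and 0.679 CPM in control and 0.285, 0.311 and 0.199 CPM in resveratrol. Icos, a costimulatory receptor, was at 2.14 ± 0.744 and 0.680 ± 0.185 CPM, whereas Ikzf2 differed by 0.060 ± 0.085. Ikzf2, at 161 ± 13.3 and 168 ± 8.32 CPM, lay far above the other tested members. Bulk tissue does not show which cells expressed it, so it is no measure of regulatory T cells here. With no filter on low counts this list missed the threshold (adjusted p = 0.0745). The 7 immune checkpoint genes fell as a list (median -0.70; camera adjusted p = 0.0109; adjusted p = 0.389 with an estimated correlation), with 0 passing adjusted over the list alone, Cd200 at -0.70 ± 0.25 and Cd200r1 at -0.31 ± 0.25. Cytotoxic T and NK cell genes (5 tested, median -1.54) did not pass by camera (adjusted p = 0.0714) but did without control 3 (adjusted p = 0.00552) or without resveratrol 3 (adjusted p = 0.0174). In that list Klrk1, an activating receptor of NK cells, differed by -1.73 ± 0.67. Cd8a, a coreceptor of cytotoxic T cells, was at 4.71, 5.31 and 3.43 CPM in control and 0.0819, 0.537 and 3.98 CPM in resveratrol libraries 1, 2 and 3, and thus overlapped between the groups. Ifng had 2 counts over all libraries and was not tested. The 3 tested B and plasma cell genes did not pass as a list (median -0.77, camera adjusted p = 0.272), with Pax5 at -0.46 ± 0.53 and Fcrla at -0.77 ± 0.38.

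Macrophage and monocyte markers had lower means in 15 of 17 members, and the list fell by camera (median -0.87; camera adjusted p = 1.99e-05; adjusted p = 0.477 with an estimated correlation). Cd68, a lysosomal protein of macrophages, was at 57.4 ± 8.60 CPM in control and 31.1 ± 7.00 CPM in resveratrol, while Lyz2 (-0.80 ± 0.46) and Cd14 (-0.25 ± 0.14) overlapped between the groups. DESeq2 called 7 of these markers, and 11 were lower adjusted over the list alone. All 12 dendritic cell markers had lower means and fell as a list (median -1.03; camera adjusted p = 4.35e-05; adjusted p = 0.389 with an estimated correlation), with Irf8, a transcription factor of dendritic cells, at -0.84 ± 0.23 and Itgax, the CD11c integrin, at -1.10 ± 0.29. Of these, 5 passed adjusted over the list alone, Flt3, Itgax, Cd86, Irf8 and Ccl22. All 11 MHC class II genes had lower means and fell as a list (median -1.26; camera adjusted p = 3.93e-06; adjusted p = 0.432 with an estimated correlation), 10 passed adjusted over the list alone and DESeq2 called 8. RT1-Da, a class II chain, was at 182 ± 87.5 and 70.1 ± 14.4 CPM; RT1 genes have similar sequences, and how shared reads were counted is not given in the sources used here, so their levels are uncertain. The 11 MHC class I processing genes (median -0.26) did not pass by camera (adjusted p = 0.0504), with B2m at -0.64 ± 0.26 and Psme1 at -0.26 ± 0.074. This list passed without control 2 (adjusted p = 0.00553), control 3 (0.0228) or resveratrol 3 (0.0142), and with DESeq2 size factors (0.0474). The 7 tested neutrophil markers did not pass as a list (median -0.53, camera adjusted p = 0.237), with S100a8 at -1.38 ± 0.45 and S100a9 at -0.92 ± 0.29. Of mast cell and eosinophil markers 2 were tested and no list test was made; Kit differed by 0.0083 ± 0.23. Hdc, which makes histamine, was at 0.0862, 0.272 and 0.0804 CPM in control and 0.218, 0.430 and 4.21 CPM in resveratrol libraries 1, 2 and 3.

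All 18 type I interferon response genes had lower means in resveratrol, and the list fell by camera (median -1.34; camera adjusted p = 1.31e-09; adjusted p = 0.389 with an estimated correlation). DESeq2 called 14 of them, and 14 were lower adjusted over the list alone. The members with the highest CPM, Ifi27 (-0.48 ± 0.21) and Ifit2 (-0.38 ± 0.17), overlapped between the groups. Isg15, a ubiquitin-like protein, and Mx2, an antiviral GTPase, were named after their values were seen; these genes spread widely within control, and control 3 was nearest to resveratrol. Isg15 was at 40.9, 32.2 and 7.56 CPM in control libraries 1, 2 and 3 and 1.83 to 3.27 CPM in resveratrol (-3.43 ± 0.60), and Mx2 was at 104, 31.8 and 3.67 CPM against 1.37 to 1.95 CPM (-4.85 ± 1.05). Mx and Oas genes belong to families of similar sequence, so their levels are uncertain where reads were shared. The 14 interferon gamma response genes fell by camera (median -0.36; camera adjusted p = 0.0357; adjusted p = 0.389 with an estimated correlation), with 0 passing adjusted over the list alone. Gbp2 was at 1855 ± 919 and 1285 ± 273 CPM and overlapped between the groups. Its values were 1322, 1327 and 2916 CPM in control and 1018, 1274 and 1563 CPM in resveratrol libraries 1, 2 and 3. Control 3 was thus its highest library. The call of the interferon gamma list was lost without control 1 (adjusted p = 0.126), without resveratrol 2 (0.0953) and in the Oct libraries alone (0.225).

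Inflammatory cytokine and mediator genes had lower means in all 16 members and fell as a list (median -0.65; camera adjusted p = 0.00213; adjusted p = 0.389 with an estimated correlation). Il1b, a pyrogenic cytokine, was at 19.0 ± 4.97 CPM in control and 11.7 ± 4.10 CPM in resveratrol and overlapped between the groups, and Tnf was at 1.53 ± 0.228 and 0.886 ± 0.0901 CPM. Il1rn, the antagonist of the interleukin 1 receptor, differed by -0.44 ± 0.11 and Il33 by -0.086 ± 0.19. Adjusted over the list alone 3 were lower, Il1rn, Il12b and Il36g. Complement genes had lower means in all 14 members and fell as a list (median -0.70; camera adjusted p = 0.000331; adjusted p = 0.389 with an estimated correlation); 3 passed adjusted over the list alone, C4a, C3ar1 and C2, while the most abundant, C1s (-0.15 ± 0.19) and C1r (-0.32 ± 0.16), overlapped between the groups. Chemokine and chemokine receptor genes (20 tested, median -0.39) did not pass by camera (adjusted p = 0.0734), with Cxcl6 at -0.031 ± 0.42, Cxcl16 at -0.057 ± 0.11 and 2 passing adjusted over the list alone, Cxcl13 and Cxcl12. They passed without control 1 (adjusted p = 0.0221), control 3 (0.0197) or resveratrol 3 (0.0281), and in the Oct libraries alone (0.0294). NF-kB pathway genes had higher means in 5 of 15 members and did not pass (median -0.15, camera adjusted p = 0.225), with Nfkb1 at 0.23 ± 0.073 and Vcam1 at 0.14 ± 0.24.

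Blood vessel endothelial markers had lower means in all 14 members and fell as a list (median -0.67; camera adjusted p = 1.18e-05; adjusted p = 0.432 with an estimated correlation). Eng, a TGF-beta coreceptor, was at 129 ± 20.7 CPM in control and 77.6 ± 8.38 CPM in resveratrol, Pecam1 differed by -0.74 ± 0.22 and Erg, an endothelial transcription factor, by -0.21 ± 0.13. Of the vessel markers 8 were lower adjusted over the list alone, and DESeq2 called 6. Angiogenic and lymphangiogenic factors had lower means in 13 of 16 members and fell as a list (median -0.43; camera adjusted p = 0.0135; adjusted p = 0.432 with an estimated correlation), with 5 passing adjusted over the list alone, Nrp1, Angpt1, Pgf, Flt1 and Angpt2. Vegfc, a lymphangiogenic growth factor, was at 6.55 ± 0.497 and 4.65 ± 0.671 CPM. Vegfa, the main angiogenic factor, overlapped between the groups at 67.2 ± 38.4 and 78.3 ± 47.7 CPM (0.22 ± 0.51), as did Hif1a (0.30 ± 0.17) and Thbs1 (-0.37 ± 0.39). This list's call was lost without control 2 (adjusted p = 0.0907) and without resveratrol 2 (adjusted p = 0.0622). Lymphatic endothelial markers (8 tested, median -0.38) did not pass by camera (adjusted p = 0.0639), with Lyve1 at -0.29 ± 0.24, Pdpn at 0.15 ± 0.17, Nr2f2 at -0.049 ± 0.13 and 2 passing adjusted over the list alone, Tbx1 and Sox18. They passed without control 3 (adjusted p = 0.00537), without resveratrol 3 (0.0108) or with no filter on low counts (0.0459).

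Extracellular matrix and fibrosis genes had lower means in 15 of 16 members and fell as a list (median -0.60; camera adjusted p = 1.29e-05; adjusted p = 0.389 with an estimated correlation). Col1a1 differed by -0.97 ± 0.27, and Col1a2, its partner chain in type I collagen, was at 4468 ± 1026 CPM in control and 2381 ± 565 CPM in resveratrol. Adjusted over the list alone 10 were lower, and DESeq2 called 8. Matrix proteases and inhibitors had lower means in all 15 members and fell as a list (median -0.48; camera adjusted p = 0.000703; adjusted p = 0.389 with an estimated correlation), with Mmp14, a membrane-bound collagenase, at 628 ± 73.1 and 399.8 ± 31.5 CPM and Mmp2, a gelatinase, at 878 ± 137 and 571 ± 104 CPM. Of these, 7 were lower adjusted over the list alone, and DESeq2 called 6.

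**Figure D3:**
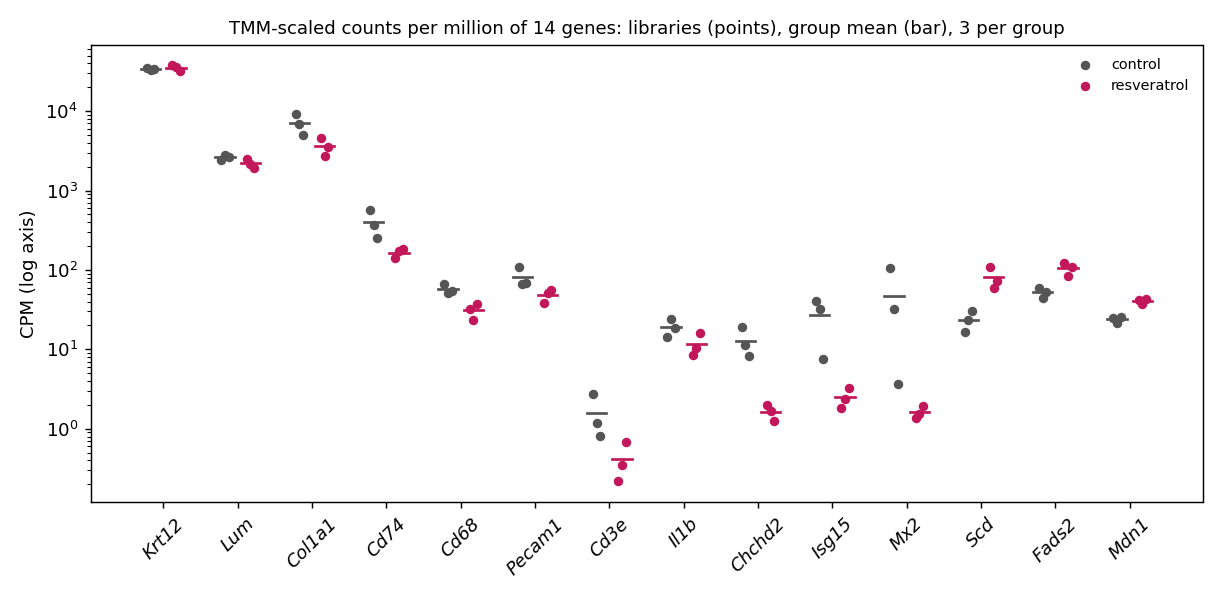
CPM on a log axis of 14 genes in each library (points; gray control, red resveratrol) with the group mean (bar, n = 3). Krt12 overlaps between the groups (34169 ± 1076 CPM in control), Cd74, Cd68, Pecam1, Cd3e and Col1a1 lie lower in all resveratrol libraries, Isg15 and Mx2, chosen after their values were seen, spread widely within control, and Scd, Fads2 and Mdn1 lie higher.

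Resident cornea markers did not pass as lists by camera or by fry's directional test. The corneal endothelial list passed fry's test for change in either direction (adjusted p = 0.0422). Corneal epithelial markers had higher means in 10 of 13 members, by a median of 0.061 (camera adjusted p = 0.285), with Krt12 at 0.038 ± 0.26 and Krt5 at 0.032 ± 0.24. These standard errors are moderated over genes and are not the spread of each keratin's own libraries. Keratocyte markers (10 tested) had a median of -0.20 (adjusted p = 0.305), with Lum at -0.26 ± 0.14 and Dcn, also a stromal proteoglycan, at -0.071 ± 0.21. Corneal endothelial markers went both ways (13 tested, median -0.034, adjusted p = 0.787), with Aqp1, a water channel, at -0.034 ± 0.12. Adjusted over the list alone, 1 of these was higher, Alcam (0.60 ± 0.11), and 2 were lower, Cdh2 (-1.27 ± 0.28) and Col8a1 (-0.72 ± 0.17). Keratinization genes (13 tested, median -0.20, adjusted p = 0.225) included Krt6a at -0.076 ± 0.14 and Krt17 at -0.59 ± 0.38. Conjunctival and goblet cell genes (5 tested, median -0.18, adjusted p = 0.433) included Krt13 at -0.18 ± 0.20 and Krt4 at -0.43 ± 0.31.

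Markers of neighbouring tissues did not pass as lists either. Iris and pigment cell markers (5 tested) had a median of -0.12 (camera adjusted p = 0.696), with Gpnmb at -0.12 ± 0.11 and Dct at -0.071 ± 0.58. Erythrocyte genes (4 tested) had a median of -0.42 (adjusted p = 0.433), with the globins Hba-a1 at -0.44 ± 0.38 and Hbb at -0.40 ± 0.46, which have near-identical copies and are uncertain, and passed without control 2 (adjusted p = 0.0359). Lens genes (7 tested) had a positive median (0.11) and mean (0.16) while the test pointed down (adjusted p = 0.870), with Cryab at 0.11 ± 0.55 and Bfsp1 at 0.13 ± 0.19. Schwann cell and nerve genes (9 tested) had a median of 0.030 and a mean of -0.22 while the test pointed up (adjusted p = 0.870), with Mbp at 0.13 ± 0.10 and Pmp22 at -0.14 ± 0.096. The retina list had 2 tested members, Gnat1 (0.50 ± 0.47) and Rom1 (-0.15 ± 0.26), and the skeletal muscle list 2, Tnni2 (0.094 ± 0.20) and Tnnt3 (-0.60 ± 0.28), too few for a list test; with no filter on low counts the retina list passed, higher in resveratrol. Of the sex-linked list 1 gene was in the table and was not tested, and the mitochondrially encoded list had no member in the table.

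Cell cycle genes had higher means in 19 of 20 members and rose as a list (median 0.33; camera adjusted p = 0.000675; adjusted p = 0.657 with an estimated correlation). Pcna, the replication clamp, was at 84.1 ± 13.7 CPM in control and 115 ± 7.21 CPM in resveratrol (edgeR adjusted p = 0.146, DESeq2 0.0344), and Mki67, a proliferation marker, differed by 0.52 ± 0.35. No member passed adjusted over the list alone, and without resveratrol 3 the list missed the threshold (adjusted p = 0.0739). Sirtuin and PGC-1 axis genes (14 tested), a pathway often linked with resveratrol, had a median of 0.042 (camera adjusted p = 0.397), with Sirt1 at 17.9 ± 1.04 and 20.1 ± 3.09 CPM, Foxo1 at 0.16 ± 0.12 and Foxo3 at 0.00033 ± 0.10. Adjusted over the list alone 1 of them was higher, Ppargc1b (0.89 ± 0.20). NRF2 and antioxidant genes (16 tested) had a median of 0.044 (adjusted p = 0.939), with Prdx1 at -0.21 ± 0.095 and Gpx2 at 0.47 ± 0.32. Aryl hydrocarbon receptor targets (4 tested) had a median of 0.20 (adjusted p = 0.706), with Ahr at 0.17 ± 0.15 and Tiparp at 0.23 ± 0.20. Apoptosis and growth arrest genes (14 tested) had a median of -0.060 (adjusted p = 0.689), with Bcl2l1 at 0.16 ± 0.16. Heat shock genes (9 tested) had a median of 0.19 (adjusted p = 0.433), with Hspa8 at 0.22 ± 0.11 and Hspb1 at -0.27 ± 0.085. Immediate early genes (12 tested) had a median of -0.19 (adjusted p = 0.386), with Junb at -0.076 ± 0.26 and Dusp1 at -0.14 ± 0.49, and passed without control 1 (adjusted p = 0.0167) and in the Oct libraries alone (adjusted p = 0.000230).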

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

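The DESeq2 fits under other designs or without a library, the likelihood ratio test, the bias-adjusted deviances and the gene length correction were chosen after the data were seen. With edgeR's quasi-likelihood test the count of genes was 0 at an adjusted p of 0.05 under every scaling, filter, robust, covariate, Oct and gene length setting tried, and 0 at thresholds of 0.01 and 0.1 in the main setting, with 2782 genes at an unadjusted p under 0.05 there. The smallest adjusted p was under 0.1 with upper-quartile factors (0.0936), no filter (0.0864) and the strict filter (0.0957), and limma voom and limma on FPKM also gave 0. DESeq2 called 1007 genes (327 genes higher in resveratrol, 680 genes lower in resveratrol, 274 at least 2-fold) and the likelihood ratio test 829 (192, 637 and 298). In the simulated counts DESeq2 also called more unchanged genes than edgeR did (41 of 185 calls against 6 of 121). Whether this accounts for the gap to edgeR's 0 calls was not tested. Leaving out each library gave 0 to 21 genes with edgeR, 0 to 0 higher, 0 to 21 lower and 0 to 21 at least 2-fold, highest without control 3. With DESeq2 it gave 390 to 1042 genes, 95 to 329 higher, 295 to 713 lower and 150 to 376 genes changed at least 2-fold by DESeq2, and 363 of the 390 genes called without control 2 were among the 1007. In the Oct libraries alone DESeq2 called 404 (112 higher, 292 lower, 112 at least 2-fold), with fewer samples. Samples with the same replicate number did not deviate together (correlations across genes of -0.00442, -0.0123 and -0.0225), and no library correlated best with its own number, so the numbers were not taken to pair them; replicate 1 of both groups also shares the Sep ending and replicates 2 and 3 the Oct ending. With the replicate block edgeR called 0 genes, camera 15 lists and DESeq2 672 genes, 217 higher and 173 at least 2-fold. The count of lists that moved was 0 with an estimated correlation and 0 by fry's directional test, and 13 to 19 without each library. Depth limits the genes with few counts.

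Among the named genes, 2270 values kept their direction and side of the threshold, 76 passed it under an alternative, and 66 changed sign. None of those that changed sign passed the threshold in any fit that reversed it, and the cause was not tested. In the Oct libraries alone the log2 fold changes were Cryab -0.065, Cxcl16 0.12, Foxo3 -0.13, Gpx2 -0.16, Krt6a 0.026, Lyz2 0.10, Nr2f2 0.095, Pax5 0.41, Vcam1 -0.22 and Vegfa -0.67. With limma voom they were Cxcl6 0.052 and Dusp1 0.085; with the replicate block Cxcl6 0.065 and Dusp1 0.086; on log2(FPKM + 1), with and without a filter, Cxcl6 0.066, Dct 0.00099 and Dusp1 0.097; on log2(FPKM + 0.1) Cxcl6 0.068, Dct 0.027 and Dusp1 0.10. Removing the length trend gave Cxcl6 0.016 and Foxo3 -0.026, upper-quartile factors gave Foxo3 -0.023 and Kit -0.017 and the strict filter gave Foxo3 -0.0075 and Kit -3.1e-05. Leaving out each library gave ranges of -0.10 to 0.089 for Aqp1, -0.0089 to 0.27 for Bfsp1, -0.33 to 0.034 for C1s, -0.30 to 0.46 for Cryab, -0.11 to 0.040 for Cxcl16, -0.41 to 0.59 for Cxcl6, -0.25 to 0.13 for Dcn, -0.53 to 0.71 for Dct, -0.45 to 0.74 for Dusp1, -0.086 to 0.058 for Foxo3, -0.0061 to 0.11 for Ikzf2, -0.24 to 0.19 for Il33, -0.31 to 0.17 for Junb, -0.19 to 0.24 for Kit, -0.0066 to 0.11 for Krt12, -0.052 to 0.11 for Krt5, -0.12 to 0.028 for Krt6a, -0.17 to 0.078 for Nr2f2, -0.86 to 0.29 for Pax5, -0.33 to 0.052 for Rom1, -0.71 to 0.052 for Thbs1, -0.011 to 0.26 for Tnni2, -0.065 to 0.37 for Vcam1 and -0.37 to 0.77 for Vegfa.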

Other observations

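All tests in this part except those of the lists that moved over other splits, the lower leukocyte markers of control 3, the sterol members not looked at before and the gene length of all sterol members were chosen only after the result was seen. Genes of sterol and fatty acid synthesis, a group not among the lists above, had higher means in resveratrol. Of 40 such genes, 18 were taken from the higher DESeq2 calls, so their direction was fixed by that choice, and the other 22 were known only not to be among those calls. Of these 22, 21 had a log2 fold change above 0 (median 0.29), and edgeR called 0 of the 40 after adjustment. Besides Scd and Fads2, Fasn, the fatty acid synthase, differed by 0.48 ± 0.095. Fasn was named after its values were seen.

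Ribosome biogenesis genes, listed after Mdn1 and Heatr1 had been seen, had higher means in 25 of 26 members (median 0.25; camera adjusted p = 5.34e-08 over 5 lists; unadjusted p = 0.124 with an estimated correlation). Nop56, a core protein of small nucleolar ribonucleoproteins, differed by 0.48 ± 0.18 and Rrs1 by 0.48 ± 0.18, and DESeq2 called 0 of the members, which were known beforehand not to be among its calls.

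The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. edgeR called 0 genes in the real split and at most 0 in the others; with a real count of 0 all 10 splits give as many, so this count shows nothing. At an unadjusted p under 0.05 the real split gave 2782 and the highest other 847. DESeq2 called 1007 in the real split and at most 45 in the others (1 of 10 as large). Camera with the preset correlation moved 15 lists in the real split and 17 in the split of control 1, control 2 and resveratrol 3 against the rest (2 of 10 as large).

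Macrophage, dendritic cell, T cell, vessel and matrix lists were lower in resveratrol by camera with the preset correlation, while with an estimated correlation and by fry's directional test 0 lists passed. A larger epithelial share of the tissue would lower all non-epithelial types alike. The macrophage median instead lay below the keratocyte median (difference -0.67 on the log2 scale, 95% bootstrap interval over genes -0.84 to -0.44). That interval treats genes as independent and leaves out the spread between libraries. The argument against this share as the whole cause therefore covers these 6 libraries only. A part is not argued against, since keratocyte markers had lower means in 9 of 10 members and epithelial markers higher means in 10 of 13. Fold changes had a trend with gene length, with a median log2 fold change of -0.092 in the shortest decile of genes and 0.064 in the longest. With this gene length trend removed, 15 lists were called as before, which argues against length bias as the whole cause. Fewer infiltrating cells and lower transcription per cell both stay open, since bulk tissue holds no value that separates them, and a treatment effect remains a hypothesis.

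Type I interferon genes were low in control 3 beside the other controls. A difference between Sep and Oct libraries would not by itself separate control 2 from control 3, both Oct libraries. Control 2 was above control 3 in 18 of 18 genes, which restates the pattern and compares 1 library with another. A wrong label of control 3 cannot be told apart from biological spread: on genes called by DESeq2 without it, interferon genes left out, it lay at 0.514 on a scale from 0 (the other controls) to 1 (resveratrol), between the held-out controls (0.208 and 0.227) and the lowest held-out resveratrol library (0.582), a gap under the SD of the resveratrol positions (0.119), and that SD was added to the bound after the position was seen. Whether fewer leukocytes in control 3 account for it cannot be told. Against the other controls, control 3 had a median of -1.02 for interferon genes and -0.60 for leukocyte markers. The difference of -0.42 has a 95% interval over genes (-0.87 to 0.11) that includes 0 and leaves out the spread between libraries.

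Sterol and fatty acid synthesis genes had higher means in resveratrol, and a change in the whole program is a candidate explanation. The 22 members not looked at before, known only not to be among the DESeq2 calls, were higher as a list by camera with the preset correlation (21 above 0, median 0.29, unadjusted camera p = 7.85e-07, adjusted p = 9.82e-07 over 5 lists, but unadjusted p = 0.123 with an estimated correlation). The epithelial markers lay below these 22 members by 0.23 (95% interval over genes 0.075 to 0.34), and 0.33 below all 40, a gap widened by the 18 picked as higher. In these libraries this argues against a larger epithelial share as the whole cause, though the interval leaves out the spread between libraries. Length bias is argued against by a median of 0.41 after a length trend was removed, against 0.39 before. Of the gland lipid enzymes Awat1, Awat2, Elovl3 and Dgat2l6, only Awat2 was in the count table, with a mean of 0.00885 CPM in resveratrol (1 count). The others are absent from it, for want of any count or under another symbol. Awat2 alone therefore argues against meibomian or sebaceous gland tissue. The 3 tested gland genes, which other tissues also express, had a median of -0.46 (camera adjusted p = 0.0778). A lower share of leukocyte, vessel and matrix transcripts would raise all resident cells alike. The 36 epithelial, keratocyte and corneal endothelial markers (median -0.025) instead lay below the 22 members by 0.32 (0.18 to 0.50 over genes), and 0.42 below all 40. Cell cycle genes (median 0.33) and ribosome biogenesis genes (median 0.25) were higher by similar amounts, so the rise was not particular to this program. A rise shared by several gene groups is not argued against by these markers. The program remains a hypothesis found and tested on the same data.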
